A study of Homo sapiens with 20 samples.

How the data were processed

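The series measured mRNA in MDA-MB-231, an established human breast cancer cell line, in 20 samples that fall into 5 groups of 4. Per the labels' protocols, 30000 cells per well were grown for 24 h at 37 °C, and 2 wells were pooled for each RNA sample. In 4 of the groups the cells were held for 4 h with nanoparticles at 0.1 mg/ml in 200 µl of medium. In 3 of these the wells were then lit for 10 min by an 808 nm continuous-wave laser whose temperature was held at 46, 50 or 54 °C, and the cells were washed. A time between the laser and the wash or lysis was not given in the sources used here. Libraries were made with a QuantSeq FWD kit, which primes on the poly(A) tail and reads the 3' end of mRNAs on a known strand. A group with laser light and no nanoparticles was not analysed here, so heat and light were not separated.

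The deposited table holds estimated counts per gene for each sample, made by the authors with STAR and Salmon on GRCh38, per the submitters' processing notes. Tool versions, the gene annotation behind the counts, the use of molecular identifiers and the strand setting of the counting are not given in the sources used here. The table has 36601 genes, of which 36366 identifiers were found in the reference name table, and 10 symbols belong to more than 1 identifier. Between 1.74% and 2.9% of the values in a library were not whole numbers, and all were rounded before testing. Gene positions were taken from GENCODE v29 on GRCh38. The authors may have used another annotation.

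Total counts per library ran from 2401180 to 7710977. The group means were 3386464 in untreated cells, 3800525 with nanoparticles alone, 2872173 at 46 °C, 4130926 at 50 °C and 6769582 at 54 °C. Replicates of a group correlated at 0.891 to 0.942 in log2 CPM across genes. Their counts differed by a chi-square of 7.79 to 23.56 per gene, far above sampling noise, so no library was counted as a duplicate. Reads copied by PCR are not independent molecules, so the depth of a library bounds counting error only. The 95% intervals of fold changes are from the fitted model and rest on the spread between the samples.

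Genes were tested with edgeR 4.0.16 in R 4.3.3 with a robust quasi-likelihood fit of 5 group means over all 20 samples. TMM scaling was used. The filter asked for a count of 10 in enough samples and a total of 15, which left 12149 genes holding at least 99.67% of the counts of each library. Every adjusted p is from this test with Benjamini-Hochberg adjustment over all tested genes unless another is named, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale with standard errors from the fit. CPM values are TMM-scaled, with a mean and SD over 4 samples, and log2 CPM used a prior count of 2. All comparisons have 4 samples against 4. The labels do not say that replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

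The comparisons were nanoparticles alone against untreated cells, each laser temperature against nanoparticles alone, 50 °C against 46 °C, and 54 °C against 50 °C. A difference between 54 °C and 46 °C was not tested. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 measured members, with adjustment over the lists of a comparison. Each list result was also computed with an estimated correlation. Of the 32 lists, 28 were tested: cytosolic heat shock chaperones, endoplasmic reticulum chaperones, integrated stress response, immediate-early genes, growth genes known to respond to MYC, the MYC and MAX network, checkpoint ligands, class I antigen presentation, NF-kB targets and cytokines, interferon-stimulated genes, cell death effectors, NRF2 targets, iron handling, metallothioneins, cholesterol synthesis, lysosome genes, hypoxia and glycolysis genes, G2/M genes, DNA replication genes, YAP and SRF targets, proteasome subunits, splicing regulators, ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, mitochondrially encoded mRNAs, nuclear long noncoding RNAs, replication-dependent histones, and luminal breast markers. The lists of nuclear long noncoding RNAs and of histones were fixed as signs of RNA quality. Markers of macrophages, lymphocytes, blood and fibroblasts had too few measured members for a test.

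The genes named in the text follow a rule. For each comparison against nanoparticles alone or untreated cells it takes the 8 largest rises and the 8 largest falls among called genes with a mean CPM of at least 10 over the 8 samples and no overlap between the replicate values of the groups. For each step between temperatures it takes 4 and 4. The results of a few genes are not reported here. Genes whose symbol is a clone name or an Ensembl identifier, Y-linked genes and XIST were left out. The rule adds the 3 members with the smallest p of each called list and the fixed genes MYC, MAX, CD274, CD47, HSPA1A, HSPA1B, DNAJB1, HSPH1, FOS, EGR1, ATF3, JUN, CIRBP, RBM3 and HMOX1. Groups, comparisons, tests, lists, this rule and the first set of alternatives were fixed before the data were examined.

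The alternatives fixed beforehand were size factors of DESeq2 in edgeR, scaling by library totals, no filter, a stricter filter of 5 CPM in 4 samples, the Wald test of DESeq2 1.42.0, limma-voom with sample weights, a fit of only the 8 samples compared, the replicate number as a block, a fold threshold of 1 on the log2 scale, removal of mitochondrially encoded genes, thinning to the smallest library, untreated cells as the baseline, and leaving out each library in turn. The following were added after seeing the data: a term for replicates 1 and 2 against 3 and 4, each of these pairs alone, and DESeq2 with its own filter. The gene test was tested on simulated data with 200 changed genes per comparison. At a 2-fold change it called 28.4% of the changed genes for nanoparticles alone against untreated cells (11802 genes tested), 28.4% at 46 °C (11783 genes), 37.3% at 50 °C (11817 genes) and 49.3% at 54 °C (11780 genes). For 50 °C against 46 °C it called 34.3% (11801 genes), and for 54 °C against 50 °C 26.9% (11799 genes). In the same order it called 65.2%, 71.2%, 72.7%, 72.7%, 84.8% and 63.6% at 4-fold, and 9%, 9%, 16.4%, 3%, 3% and 7.5% at 1.5-fold. Random steps used the seed 20240.

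Some genes share reads with near-identical copies, and how the counting split such reads is not stated, so their single values are uncertain. They are HSPA1A and HSPA1B, EIF3C and EIF3CL, POLR2J3, the MTRNR2L genes and the mitochondrial genes they copy, histone gene copies, and ribosomal protein genes with processed pseudogenes. Overlapping MT-ATP8 and MT-ATP6, and KCNQ1OT1 and MT-ND6, which lie opposite other transcripts, are uncertain for the same kind of reason.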

Results

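Gene counts from the 3' ends of mRNAs were compared in MDA-MB-231 cells, a human breast cancer line, under 5 conditions with 4 samples each. The groups were untreated cells, cells with nanoparticles and no laser (nanoparticles alone), and cells with nanoparticles and 10 min of 808 nm laser light at 46, 50 or 54 °C. The series title names c-MYC and immunotherapy. Library totals ran from 2401180 to 7710977 counts, and the group means from 2872173 at 46 °C to 6769582 at 54 °C. Replicates 1 and 2 differed from replicates 3 and 4 across the groups in 1072 genes, 507 higher and 565 lower in replicates 3 and 4, a division found after seeing the data. IL11 differed by −1.37 and ASNS by 1.45 on the log2 scale. They were chosen after their values were seen. The labels give no batch, so each comparison is also given within replicates 1 and 2 and within replicates 3 and 4.

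Nanoparticles alone were set against untreated cells to ask what the particles did without light. No named stress gene was called. HSPA1A, an inducible heat shock chaperone, had a log2 fold change of 0.23 ± 0.29 (SE, n = 4 per group; adjusted p = 1), HSPH1, a co-chaperone, −0.07 ± 0.15, and JUN, an immediate-early transcription factor, 0.07 ± 0.17. HMOX1, the heme-degrading enzyme, had −0.92 ± 0.65 at 2.54 ± 1.84 CPM (SD) with nanoparticles and 4.61 ± 3.35 CPM without. MAX, the partner of MYC, had 0.001 ± 0.17, CD274, which encodes the checkpoint ligand PD-L1, 0.24 ± 0.34, and CD47, a signal against phagocytosis, 0.29 ± 0.21. The intervals leave room for changes in these genes: that of HSPA1A ran from −0.38 to 0.84.

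Among 12149 genes edgeR called 0 higher and 0 lower between nanoparticles alone and untreated cells, with 479 at an unadjusted p under 0.05 and a smallest adjusted p of 1. DESeq2 called 0 with 588 at an unadjusted p under 0.05, and limma-voom 0 with 512. Replicate values of the groups did not overlap for 2.73% of genes, where chance gives 2.86%. Within replicates 1 and 2 there were 4 genes higher (HSPA1A, KHSRP, TLN1 and TMSB10) and 0 lower, and HSPA1A had 0.89 there (adjusted p = 0.0223) against −0.49 (adjusted p = 0.827) within replicates 3 and 4. Within replicates 3 and 4, ALDOA was called higher and MALAT1 lower, and the term for the replicate pairs gave 0 and 0. ALDOA was called without nanoparticle-alone replicate 1, and MTRNR2L8 without nanoparticle-alone replicate 4. KHSRP, TLN1, TMSB10, ALDOA and MTRNR2L8 were chosen after their values were seen.

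Of 28 gene lists, 5 were called between nanoparticles alone and untreated cells at the preset correlation and 0 with an estimated correlation. Of their measured members 0 passed, over all genes or adjusted over the list alone. The histone and nuclear RNA lists among them had been fixed as signs of RNA quality. The 15 replication-dependent histone genes, whose mRNAs lack a poly(A) tail, had a median of −0.73 (adjusted p = 0.00271, and adjusted p = 0.152 with an estimated correlation). Among them HIST1H1E had −0.87 ± 0.29 and HIST1H2AG −1.81 ± 0.65. The 8 nuclear long noncoding RNAs had a median of −0.34 (adjusted p = 0.0364, and adjusted p = 0.546 with an estimated correlation), with MALAT1 at −0.42 ± 0.23, NEAT1 at −0.37 ± 0.20 and KCNQ1OT1 at −0.56 ± 0.31. The 17 YAP and SRF targets, genes of the actin cytoskeleton, had a median of 0.16 (adjusted p = 0.0093, and adjusted p = 0.546 with an estimated correlation), with AMOTL2 at 0.52 ± 0.18, ZYX at 0.33 ± 0.15 and ACTB at 0.20 ± 0.09. The 13 mitochondrially encoded mRNAs had a median of 0.13 (adjusted p = 0.0093, and adjusted p = 0.974 with an estimated correlation), with MT-CO2 at 0.13 ± 0.10. The 79 ribosomal protein genes had −0.10 (adjusted p = 0.0105, and adjusted p = 0.974 with an estimated correlation), with RPL21 at −0.24 ± 0.11. Within replicates 1 and 2 and within replicates 3 and 4 the medians were −0.22 (adjusted p = 6.74e-13) and 0.033 (0.321) for ribosomal proteins, −0.026 (0.768) and 0.34 (5.54e-06) for mitochondrial mRNAs, 0.15 (0.00169) and 0.07 (0.321) for YAP and SRF targets, −0.20 (0.366) and −0.31 (0.0257) for nuclear RNAs, and −0.78 (0.103) and −0.79 (0.00172) for histones.

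Each of these 5 lists lost its call without some library. The highest adjusted p was 0.0792 for the histones, without nanoparticle-alone replicate 4, and 0.16 for the YAP and SRF targets without untreated replicate 1, with untreated replicate 2 and nanoparticle-alone replicate 4 also ending that call. It was 0.839 for ribosomal protein genes without untreated replicate 1 (also untreated replicate 2 and nanoparticle-alone replicates 1 and 3), and 0.9 for mitochondrial mRNAs without untreated replicate 4 (also nanoparticle-alone replicates 1 and 2). For the nuclear RNAs it was 0.231 without untreated replicate 3, and every other library except untreated replicate 1 and nanoparticle-alone replicate 4 ended the call too. Medians moved by over 1.5 times for the YAP and SRF targets (0.098) and ribosomal proteins (−0.033) without untreated replicate 1, for nuclear RNAs (−0.214) without untreated replicate 3, and for mitochondrial mRNAs without untreated replicate 1 (0.272), untreated replicate 4 (0.009) or nanoparticle-alone replicate 3 (0.215). The number of lists fell to 3 without untreated replicate 1 or nanoparticle-alone replicates 2, 3 or 4, and to 2 without untreated replicate 2 or nanoparticle-alone replicate 1.

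Heating at 46 °C against nanoparticles alone raised 11 of 29 measured heat shock chaperone mRNAs and 11 of 28 immediate-early mRNAs, and lowered 9 of 13 mitochondrially encoded mRNAs. Each of these lists was also called with an estimated correlation. HSPA6, a strictly inducible HSP70 gene (chromosome 1, 161524540 to 161526910, GRCh38), rose by 10.16 ± 0.73 on the log2 scale (SE, n = 4 per group; adjusted p = 3.55e-06), from 0.85 ± 1.08 to 1142 ± 405 CPM, with 15 counts in all over the libraries with nanoparticles alone. HSPA1A (chromosome 6, 31815464 to 31817946) rose by 5.93 ± 0.31 (adjusted p = 1.48e-09) and its near-identical neighbour HSPA1B by 4.69 ± 0.25 (adjusted p = 5.09e-12). Their split is uncertain, and their sum went from 63.8 ± 5.80 to 2766 ± 478 CPM. EGR1, an immediate-early transcription factor (chromosome 5, 138465490 to 138469315), rose by 6.32 ± 0.43 (adjusted p = 1.53e-07), and FOS, a subunit of AP-1, by 5.56 ± 0.91 (adjusted p = 0.00408). MT-CO3, a subunit of cytochrome oxidase encoded in mitochondrial DNA, fell by 2.03 on the log2 scale (SE 0.12; adjusted p = 4.59e-11), from 12920 ± 458 to 3161 ± 536 CPM.

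Of 29 measured genes of the heat shock list 11 rose at 46 °C, 0 fell and 18 did not pass, and 17 rose and 0 fell adjusted over the list alone. The list had a median of 0.42 and a mean of 1.33 (adjusted p = 1.43e-51, and adjusted p = 1.48e-06 with an estimated correlation). DNAJB1, the main HSP40 co-chaperone (chromosome 19, 14514770 to 14529770), rose by 3.62 ± 0.14 (adjusted p = 7.15e-27) and HSPH1 by 1.91 ± 0.15 (adjusted p = 3.21e-13). IER5, listed as an HSF1 target and not as a chaperone, rose by 2.43 ± 0.14 (adjusted p = 2.38e-20). The summed level of the list was 26610 ± 2750 CPM at 46 °C against 13300 ± 298 CPM with nanoparticles alone. Of 28 immediate-early genes 11 rose, 1 fell and 16 did not pass, and 14 rose and 1 fell adjusted over the list alone (median 0.70; adjusted p = 5.34e-27, and adjusted p = 4.56e-06 with an estimated correlation). GADD45B rose by 2.72 ± 0.20 (adjusted p = 4.13e-15), JUN by 2.01 ± 0.18 (adjusted p = 2.02e-10) and FOSB, another AP-1 subunit, by 3.97 ± 0.74 (adjusted p = 0.0014). This median was 1.151 and 1.094 without nanoparticle-alone replicates 1 and 2. The member that fell was CCN1, a matricellular protein gene, at −0.44 ± 0.11 (adjusted p = 0.0349), chosen after its value was seen. ATF3 had 1.25 ± 0.57 (adjusted p = 0.401) and HMOX1 2.16 ± 0.64 (adjusted p = 0.102). The cold-inducible RNA-binding genes CIRBP and RBM3 had −0.008 ± 0.19 and 0.42 ± 0.13 (adjusted p = 0.995 and 0.146). The nuclear long noncoding RNAs, a sign of RNA quality, had a median of 0.79 in the same comparison.

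**Figure D1:**
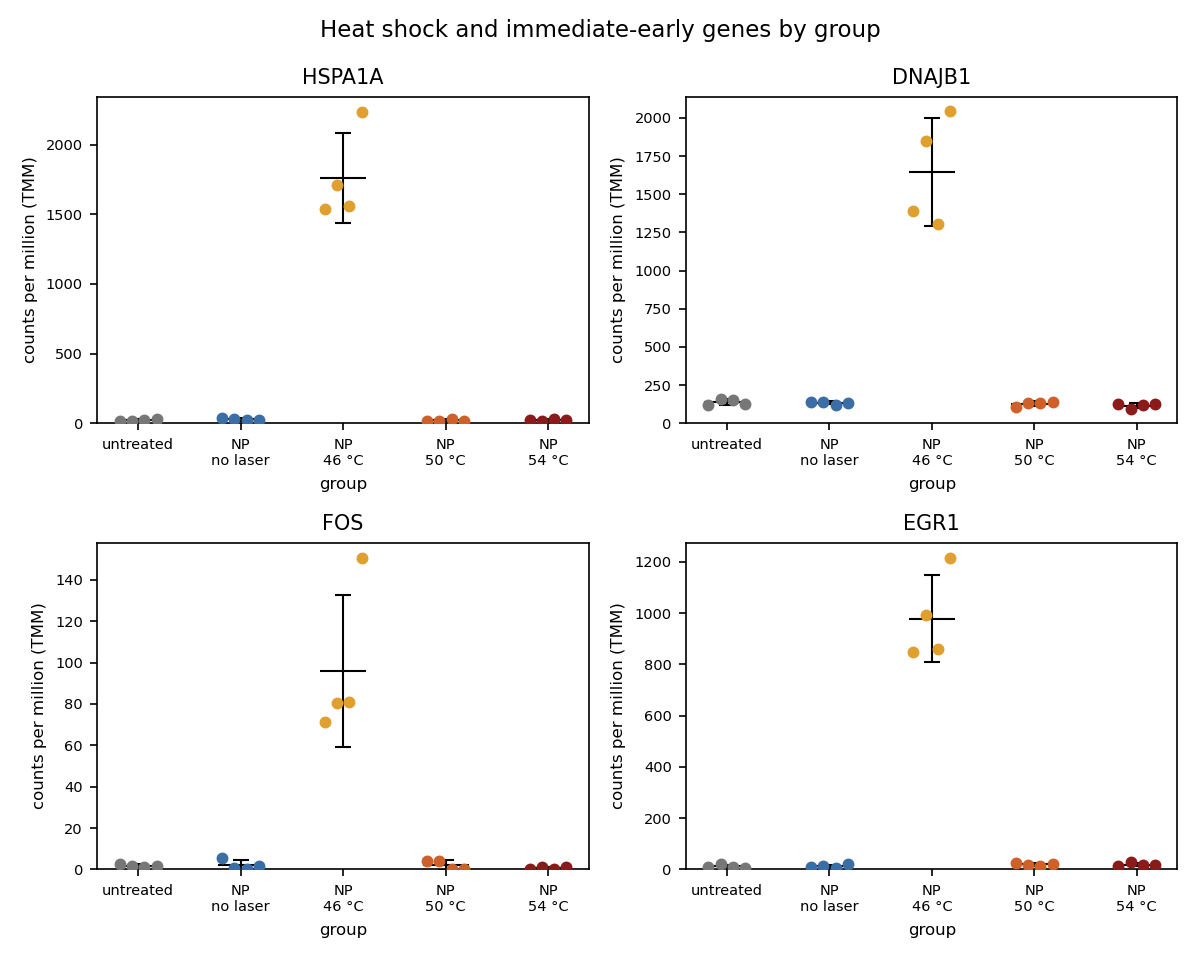
Normalised counts of HSPA1A, DNAJB1, FOS and EGR1 in CPM (vertical axes, linear from 0) in the 5 groups (horizontal axes), with a point per sample and bars for the mean and SD of 4 samples. At 46 °C the mean of DNAJB1 was 1645 CPM against 133.7 CPM with nanoparticles alone, and 128.6 CPM at 50 °C.

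Of the 13 mitochondrially encoded mRNAs 9 fell at 46 °C, 0 rose and 4 did not pass, and 13 fell adjusted over the list alone (median −1.24; adjusted p = 3.22e-78, and adjusted p = 5.34e-05 with an estimated correlation). MT-ND3 fell by 1.80 (SE 0.15; adjusted p = 4.59e-07), MT-CO2 by 1.69 (SE 0.10; adjusted p = 8.77e-15), MT-ATP8 by 1.93 (SE 0.17; adjusted p = 3.2e-06) and MT-ATP6 by 1.57 (SE 0.16; adjusted p = 9.65e-06). The share of counts on these mRNAs was 4.95% ± 0.522 (SD, n = 4) at 46 °C against 11.98% ± 0.629 with nanoparticles alone. ID1 and ID3, inhibitors of basic helix-loop-helix transcription factors, fell by 1.55 (SE 0.18; adjusted p = 6.2e-09) and 1.71 (SE 0.23; adjusted p = 7.66e-07). OGT, the O-GlcNAc transferase, fell by 1.37 (SE 0.34; adjusted p = 0.0237). RMRP, the RNA of the RNase MRP complex and itself a small structured RNA (chromosome 9, 35657751 to 35658018), rose by 5.47 ± 0.90 (adjusted p = 0.00467) from 0, 0, 11 and 7 counts with nanoparticles alone, and the noncoding LINC00324 (chromosome 17, 8220642 to 8224043) by 3.99 ± 0.35 (adjusted p = 4.59e-07). Of 8 nuclear long noncoding RNAs 3 rose, 0 fell and 5 did not pass, with 3 rising adjusted over the list alone (median 0.79; adjusted p = 3.58e-06, and adjusted p = 0.00822 with an estimated correlation). These were KCNQ1OT1 (2.10 ± 0.31; adjusted p = 5.18e-06), NEAT1 (1.20 ± 0.20; adjusted p = 9.15e-05) and MALAT1 (1.09 ± 0.23; adjusted p = 0.0313). NEAT1 and MALAT1 hold annotated structured RNA elements on their strand. This sign of RNA quality thus moved in the comparison in which heat shock mRNAs rose and mitochondrial mRNAs fell.

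The other lists called at 46 °C did not hold with an estimated correlation. Of 15 histone genes 0 passed over all genes and 2 rose adjusted over the list alone (median 0.74; adjusted p = 0.00635, and adjusted p = 0.0996 with an estimated correlation), with HIST1H4H at 2.47 ± 0.87 (adjusted p = 0.204), HIST1H2AG at 1.86 ± 0.65 (adjusted p = 0.204) and HIST1H4C at 0.63 ± 0.24 (adjusted p = 0.283). Of 79 ribosomal protein genes RPL22 alone rose (0.46 ± 0.10; adjusted p = 0.00743), with 10 higher and 3 lower adjusted over the list alone (median 0.13; adjusted p = 0.0145, and adjusted p = 0.911 with an estimated correlation). Of 50 nuclear-encoded oxidative phosphorylation genes 3 rose and 0 fell, with 4 higher adjusted over the list alone (median 0.12; adjusted p = 0.0145, and adjusted p = 0.911 with an estimated correlation). They were UQCRQ (0.45 ± 0.11; adjusted p = 0.0172), COX6C (0.48 ± 0.12; adjusted p = 0.027) and ATP5F1E (0.39 ± 0.10; adjusted p = 0.0348). MALAT1 kept its call only without nanoparticle-alone replicate 3, with an adjusted p up to 0.109. OGT lost its call without nanoparticle-alone replicates 1 or 4 or 46 °C replicates 1 or 4 (up to 0.123), and RPL22 without nanoparticle-alone replicate 4 or 46 °C replicate 2 (up to 0.0873). UQCRQ (up to 0.145), COX6C (up to 0.212) and ATP5F1E (up to 0.26) lost theirs without 46 °C replicates 1 or 2 or nanoparticle-alone replicates 2 or 4, and UQCRQ and ATP5F1E also without nanoparticle-alone replicate 1, ATP5F1E also without nanoparticle-alone replicate 3. Without 46 °C replicate 2 the adjusted p was 0.0677 for the histones (median 0.477, and 0.493 without 46 °C replicate 3), 0.256 for the ribosomal proteins (median 0.071) and 0.215 for the oxidative phosphorylation genes. Nanoparticle-alone replicate 4 also ended the histone call, nanoparticle-alone replicate 3 the other 2, and 46 °C replicate 1 the oxidative phosphorylation call.

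In all, 75 genes rose and 42 fell at 46 °C, 43 and 20 of them by at least 2-fold, and replicate values did not overlap for 6.96% of genes (chance 2.86%). Within replicates 1 and 2 the counts were 147 and 114, within replicates 3 and 4 45 and 19, and with the term for the replicate pairs 157 and 106. DESeq2 called 115 and 77. The heat shock, immediate-early, mitochondrial and nuclear RNA lists were called within each pair of replicates. Ribosomal proteins (median 0.20 and 0.042; adjusted p = 5.01e-05 and 0.836) and oxidative phosphorylation genes (0.14 and 0.12; 0.00104 and 0.208) were called within replicates 1 and 2 alone, and histones (0.91 and 0.92; 0.051 and 0.0736) within neither pair. The share of calls that were higher was 64.1%, and 74.2% when libraries were scaled by their totals. The 42 lower genes became 27 without nanoparticle-alone replicate 4 and 26 without 46 °C replicate 1. Of 28 named genes called, 22 kept the call without each of the 8 libraries in turn.

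Heating at 50 °C against nanoparticles alone raised 2 of 15 measured histone genes, 2 of 8 nuclear long noncoding RNAs and 6 of 13 mitochondrially encoded mRNAs. The histone list, but not the mitochondrial and nuclear RNA lists, was also called with an estimated correlation. RMRP rose by 5.70 ± 0.90 (SE, n = 4 per group; adjusted p = 0.0033) and LINC00324 by 4.70 ± 0.36 (adjusted p = 9.92e-08), from 10.1 ± 2.38 to 259.5 ± 52.1 CPM. ZNF277, a zinc finger gene whose span holds the small RNA copy RN7SKP187 (chromosome 7, 112206588 to 112343096), rose by 3.73 ± 0.29 (adjusted p = 8.14e-14). CSKMT, the citrate synthase methyltransferase, which spans SNORA57, rose by 3.26 ± 0.26 (adjusted p = 1.24e-13), and SNHG12, a host transcript of snoRNAs, by 3.26 ± 0.30 (adjusted p = 1.23e-06). LRRC58, a leucine-rich repeat gene, fell by 1.37 (SE 0.17; adjusted p = 1.11e-07). The heat shock list was not called at 50 °C (adjusted p = 0.383), and DNAJB1 had −0.06 ± 0.13 (adjusted p = 0.936). The list was lower within replicates 1 and 2 (median −0.096; adjusted p = 0.0366). The immediate-early list missed the threshold (median 0.16; adjusted p = 0.0554), with 1 of 28 members rising, CCN1 (0.86 ± 0.11; adjusted p = 7.39e-07, chosen after its value was seen). It was called higher within replicates 1 and 2 (adjusted p = 0.00646), with the term for the pairs (0.0161) and without nanoparticle-alone replicates 3 or 4 or 50 °C replicate 4 (0.0363, 0.0434 and 0.0418).

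Of 15 histone genes 2 rose at 50 °C, 0 fell and 13 did not pass, and 10 rose adjusted over the list alone (median 2.03; adjusted p = 1.18e-16, and adjusted p = 8.72e-05 with an estimated correlation). These were HIST1H2AG (4.08 ± 0.66; adjusted p = 6.08e-05) and HIST1H1E, a linker histone (1.86 ± 0.29; adjusted p = 3.3e-05), and HIST1H4C had 0.99 ± 0.24 (adjusted p = 0.0556). The histone and nuclear RNA lists, both signs of RNA quality, moved in the comparison in which mitochondrial mRNAs rose. Of the 13 mitochondrial mRNAs 6 rose, 0 fell and 7 did not pass, with 11 rising adjusted over the list alone (median 0.61; adjusted p = 1.17e-16, and adjusted p = 0.102 with an estimated correlation). MT-ND2 rose by 0.80 ± 0.11 (adjusted p = 0.000134), MT-CO2 by 0.54 ± 0.10 (adjusted p = 0.00138) and MT-CO3 by 0.61 ± 0.12 (adjusted p = 0.00741), and the share of counts on these mRNAs was 17.01% ± 1.95. MTRNR2L10, a nuclear copy of a mitochondrial RNA, rose by 2.86 ± 0.57 (adjusted p = 0.00193), with reads that its mitochondrial source may share. EIF3C rose by 3.69 ± 0.64 (adjusted p = 0.00709), an uncertain value, since its sum with the copy EIF3CL went only from 313.9 ± 11.6 to 397.2 ± 33.0 CPM.

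Of 8 nuclear long noncoding RNAs 2 rose at 50 °C, both also adjusted over the list alone (median 0.33; adjusted p = 0.00487, and adjusted p = 0.107 with an estimated correlation). They were NEAT1 (chromosome 11, 65422774 to 65445540; 1.44 ± 0.20; adjusted p = 2.53e-06) and MALAT1 (1.25 ± 0.23; adjusted p = 0.0128), and PVT1 had 0.58 ± 0.24 (adjusted p = 0.295). The median was 0.619 without nanoparticle-alone replicate 4, and 0.214 (adjusted p = 0.0189) when libraries were scaled by their totals. Of 24 NF-kB targets 2 rose, 0 fell and 22 did not pass, with 4 rising adjusted over the list alone (median 0.53; adjusted p = 1.42e-05, and adjusted p = 0.106 with an estimated correlation). NFKBIZ, an inducible IkB protein, rose by 1.72 ± 0.41 (adjusted p = 0.0191) with overlapping replicate values, the interferon regulatory factor IRF1 by 0.91 ± 0.22 (adjusted p = 0.0193), and IL1A had 1.18 ± 0.34 (adjusted p = 0.0633). Of 79 ribosomal protein genes 3 rose and 0 fell, with 6 rising adjusted over the list alone (median 0.10; adjusted p = 0.000872, and adjusted p = 0.711 with an estimated correlation), and scaling by library totals turned this median to −0.024 (adjusted p = 0.283). Among them were RPL12 (0.50 ± 0.10; adjusted p = 0.00283) and RPSA (0.40 ± 0.10; adjusted p = 0.0237), each spanning snoRNAs on its strand. HMOX1 had 2.31 ± 0.64 (adjusted p = 0.0554).

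Among the falls at 50 °C were IER5L (−1.76 ± 0.36; adjusted p = 0.00244), ZNF431 (−1.54 ± 0.37; adjusted p = 0.0193), ZMAT3, a p53 target (−1.47 ± 0.34; adjusted p = 0.0119), GATA2, a transcription factor (−1.45 ± 0.36; adjusted p = 0.0252), AP1S3 (−1.33 ± 0.33; adjusted p = 0.0256), DDIT4, a stress-induced inhibitor of mTORC1 (−1.28 ± 0.29; adjusted p = 0.0297), and TNRC6C, a microRNA silencing factor (−1.26 ± 0.33; adjusted p = 0.0338). Of these only IER5L kept its call without each library. DDIT4 kept it only without 50 °C replicate 2 (adjusted p up to 0.122) and TNRC6C only without nanoparticle-alone replicate 3 (up to 0.132). GATA2 lost it without nanoparticle-alone replicates 1, 2 or 3 or 50 °C replicates 1 or 3 (up to 0.132), and AP1S3 kept it only without nanoparticle-alone replicate 1 or 50 °C replicate 1 (up to 0.116). ZNF431 lost it without nanoparticle-alone replicates 2 or 3 or 50 °C replicates 1 or 2 (up to 0.104), and ZMAT3 without nanoparticle-alone replicates 3 or 4 or 50 °C replicate 1 (up to 0.0875). Among the rises, NFKBIZ lost it without nanoparticle-alone replicates 2, 3 or 4 or 50 °C replicates 1 or 2 (up to 0.104), and IRF1 without nanoparticle-alone replicates 2 or 3 or 50 °C replicate 1 (up to 0.132). RPSA kept it only without nanoparticle-alone replicate 2 or 50 °C replicate 3 (up to 0.121). RPL12 and MALAT1 lost it without nanoparticle-alone replicate 2 (0.0512 and 0.0502).

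In all, 64 genes rose and 84 fell at 50 °C, 34 and 21 of them by at least 2-fold, and replicate values did not overlap for 8.33% of genes (chance 2.86%). Within replicates 1 and 2 the counts were 95 and 123, within replicates 3 and 4 40 and 21, and with the term for the replicate pairs 150 and 180. DESeq2 called 140 and 148. Within each pair of replicates the called lists kept their sign and were called, except ribosomal proteins in replicates 3 and 4 (median 0.082; adjusted p = 0.0634, against 0.13 and 5.4e-06 in replicates 1 and 2). Scaling by library totals moved the median of all genes to −0.102 (0.018 with TMM) and the share of higher calls from 43.2% to 18.1%. The 84 lower genes became 38 without nanoparticle-alone replicate 2, 46 without its replicate 3, 47 without its replicate 4, and 33, 40 and 54 without 50 °C replicates 1, 2 and 3. The 5 called lists became 10 without nanoparticle-alone replicate 3, 9 without its replicate 4 and 8 without 50 °C replicate 2.

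Heating at 54 °C against nanoparticles alone raised 9 genes and lowered 6. BCL6, a transcriptional repressor (chromosome 3, 187721377 to 187745727), fell by 3.01 on the log2 scale (SE 0.23, n = 4 per group; adjusted p = 2.74e-14), from 91.2 ± 13.2 to 11.3 ± 3.03 CPM. NEAT1 rose by 2.04 ± 0.20 (adjusted p = 6.1e-10), ZNF277 by 1.78 ± 0.28 (adjusted p = 0.000146) and CCN1 by 0.62 ± 0.11 (adjusted p = 0.00224), and PPP3R1, the regulatory subunit of calcineurin, fell by 0.92 (SE 0.16; adjusted p = 0.00159). LINC00324 (1.94 ± 0.34; adjusted p = 0.0223), MALAT1 (1.42 ± 0.23; adjusted p = 0.0223), ZC3H12A, an RNase that degrades cytokine mRNAs (1.08 ± 0.22; adjusted p = 0.0177), POLR2J3 (1.25 ± 0.28; adjusted p = 0.0423, uncertain through its copies) and NDRG1 (0.59 ± 0.13; adjusted p = 0.0423) rose. MT-ND6 fell by 2.51 (SE 0.44; adjusted p = 0.0338) and LRRC58 by 0.73 (SE 0.16; adjusted p = 0.0386).

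**Figure D2:**
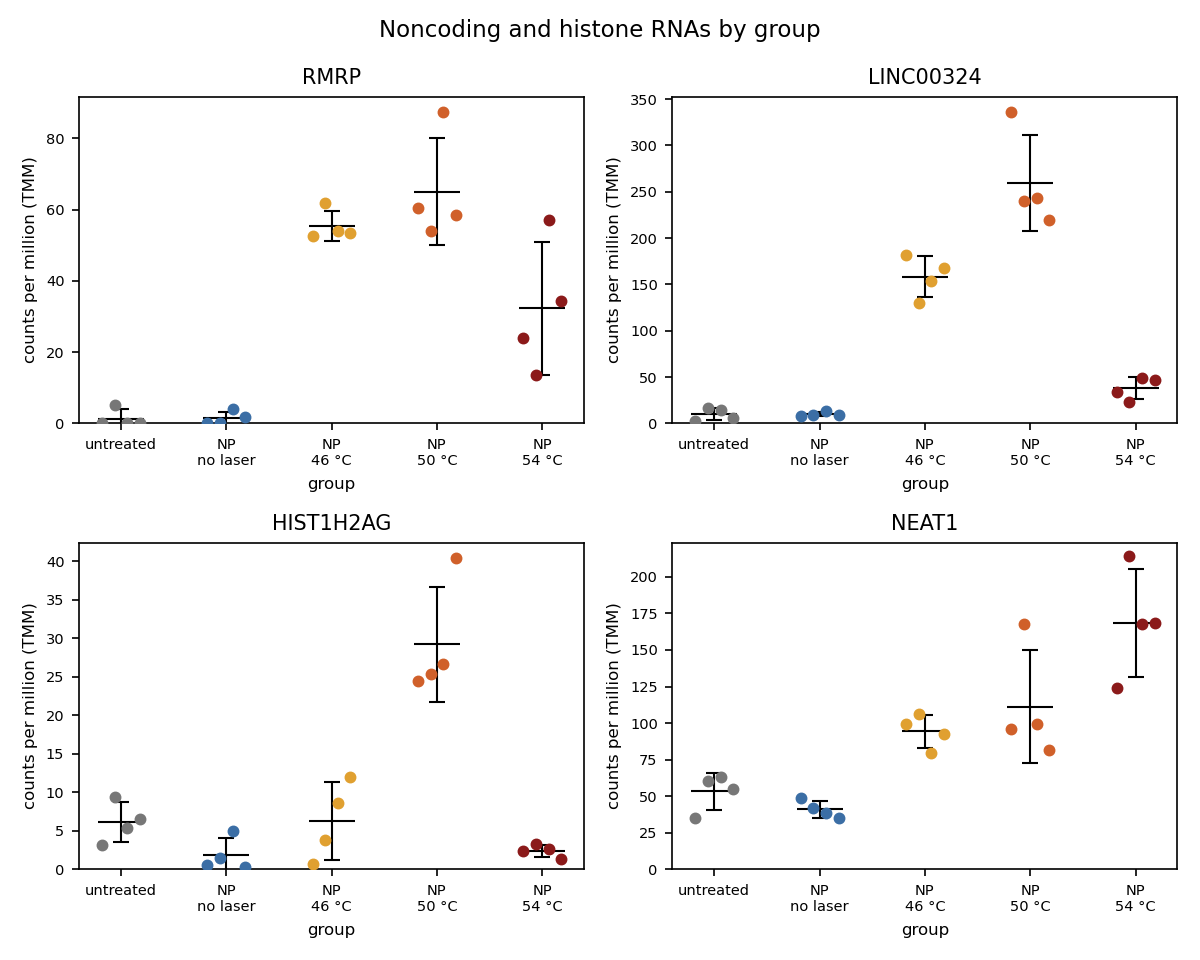
Normalised counts of RMRP, LINC00324, HIST1H2AG and NEAT1 in CPM (vertical axes, linear from 0) in the 5 groups (horizontal axes), with a point per sample and bars for the mean and SD of 4 samples. LINC00324 had a mean of 10.1 CPM with nanoparticles alone, 158.2 CPM at 46 °C, 259.5 CPM at 50 °C and 38.2 CPM at 54 °C.

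Of the 54 °C calls 7 higher and 4 lower (AC007381.2, AC109466.1, BCL6 and MT-ND6) were at least 2-fold, with 698 genes at an unadjusted p under 0.05. Calls outside the naming rule were AC007952.4 (1.46 ± 0.23), AC109466.1 (−3.89 ± 0.84) and AC007381.2 (−4.07 ± 0.36), clone-named genes chosen after their values were seen. Of 8 nuclear long noncoding RNAs 2 rose and 0 fell, with 4 rising adjusted over the list alone (median 0.55; adjusted p = 9.01e-11, and adjusted p = 0.0013 with an estimated correlation), and LINC-PINT had 1.98 ± 0.68 (adjusted p = 0.509). This list is the sign of RNA quality that moved at 54 °C, and its median was 0.844 without nanoparticle-alone replicate 4. Of 24 NF-kB targets 0 passed over all genes or adjusted over the list alone (median 0.32; adjusted p = 0.000329, and adjusted p = 0.203 with an estimated correlation), with NFKBIZ at 1.31 ± 0.41 (adjusted p = 0.37), CXCL1 at 0.71 ± 0.31 (adjusted p = 0.817) and IRF1 at 0.51 ± 0.22 (adjusted p = 0.79). The heat shock list was not called (adjusted p = 0.524), but was lower within replicates 1 and 2 (median −0.101; adjusted p = 0.0145). HSPA1A had −0.30 ± 0.28, and −0.46 ± 0.29 at 50 °C (adjusted p = 0.984 and 0.632). Within replicates 3 and 4 it had 0.21 and 0.29 (0.969 and 0.84), within 1 and 2 −0.72 and −1.23 (0.0398 and 1.65e-05). The latter share controls at 38.15 and 32.15 CPM. Untreated replicates 1 and 2 had 20.47 and 17.12, 54 °C 25.16 and 17.63, and 50 °C 16.04 and 13.9.

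The 54 °C counts within replicates 1 and 2 were 10 and 5 (AC007381.2, BCL6, HSPA1A, MT-ND6 and PPP3R1), within replicates 3 and 4 16 and 6, and with the term for the replicate pairs 26 and 17. DESeq2 called 25 and 11, and replicate values did not overlap for 4.28% of genes (chance 2.86%). Both lists were called within each pair of replicates, the nuclear RNAs with medians of 0.74 and 0.40 and the NF-kB targets with 0.45 and 0.32. Of 12 named genes called, BCL6, NEAT1, ZNF277, CCN1 and PPP3R1 kept the call without each library. LINC00324 kept it only without nanoparticle-alone replicate 3 or 54 °C replicate 2 (adjusted p up to 0.157), MALAT1 only without nanoparticle-alone replicate 3 or 54 °C replicate 1 (up to 0.0967), and MT-ND6 only without nanoparticle-alone replicates 3 or 4 (up to 0.135). POLR2J3 (up to 0.253), NDRG1 (up to 0.333) and LRRC58 (up to 0.311) kept it only without nanoparticle-alone replicate 3, and ZC3H12A lost it without nanoparticle-alone replicate 4 or 54 °C replicates 1 or 4 (up to 0.173). The 9 higher genes became 5 without nanoparticle-alone replicate 4 or 54 °C replicates 1 or 3, and 4 without 54 °C replicate 4. AC007952.4, CCN1, NEAT1 and ZNF277 were among them each time, with DGKD, MALAT1 and ZC3H12A as the fifth in the order given, and DGKD was chosen after its value was seen. The 6 lower became 3 (AC007381.2, BCL6 and PPP3R1) without nanoparticle-alone replicate 2 or 54 °C replicates 1, 2 or 3. The 2 called lists became 4 without nanoparticle-alone replicate 4 or 54 °C replicate 3, and 5 without 54 °C replicate 2.

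The step from 46 to 50 °C tested directly whether the responses differed. HSPA6 was lower at 50 °C by −9.27 ± 0.68 (SE, n = 4 per group; adjusted p = 4.24e-06), HSPA1A by −6.39 ± 0.32 (adjusted p = 5.89e-10), HSPA1B by −4.95 ± 0.26 (adjusted p = 1.66e-12), EGR1 by −5.68 ± 0.41 (adjusted p = 3.09e-07) and FOS by −5.43 ± 0.90 (adjusted p = 0.00377). Of 29 genes of the heat shock list 11 were lower, 0 higher and 18 did not pass, and 17 were lower adjusted over the list alone (median −0.49; adjusted p = 6.16e-58, and adjusted p = 7.98e-07 with an estimated correlation), with DNAJB1 at −3.68 ± 0.14 (adjusted p = 3.78e-27), IER5 at −2.57 ± 0.14 (adjusted p = 2.37e-21) and HSPH1 at −1.84 ± 0.15 (adjusted p = 9.09e-13). Of 28 immediate-early genes 10 were lower and 1 higher, with 12 lower and 1 higher adjusted over the list alone (median −0.60; adjusted p = 8.59e-17, and adjusted p = 4.09e-05 with an estimated correlation). This median was −0.921 without 46 °C replicate 3 and −1.015 without 50 °C replicate 2. GADD45B had −2.19 ± 0.20 (adjusted p = 2.39e-12) and JUN −1.78 ± 0.17 (adjusted p = 2.46e-09), and the member that was higher was CCN1 (1.30 ± 0.11; adjusted p = 1.66e-12).

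Of the 13 mitochondrial mRNAs 12 were higher at 50 °C than at 46 °C, and 13 adjusted over the list alone (median 1.91; adjusted p = 5.18e-153, and adjusted p = 1.14e-06 with an estimated correlation). MT-CO3 had 2.64 ± 0.12 (adjusted p = 3.79e-13), MT-CO2 2.23 ± 0.10 (adjusted p = 3.27e-18), MT-ND2 1.91 ± 0.12 (adjusted p = 1.88e-11) and MT-ATP8 2.80 ± 0.18 (adjusted p = 2.72e-08). MT-ND6 did not pass. SNHG12 had 3.43 ± 0.31 (adjusted p = 3.68e-07), CSKMT 3.33 ± 0.26 (adjusted p = 4.83e-14) and MTRNR2L1 2.97 ± 0.24 (adjusted p = 3.74e-08). Of 15 histone genes HIST1H1E (1.33 ± 0.29; adjusted p = 0.00432) and HIST1H2AG (2.22 ± 0.59; adjusted p = 0.0399) were higher and 0 lower, with 6 higher adjusted over the list alone (median 1.16; adjusted p = 3.98e-07, and adjusted p = 0.0034 with an estimated correlation). The histones, a sign of RNA quality, thus moved in the comparison in which heat shock mRNAs were lower and mitochondrial mRNAs higher.

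**Figure D3:**
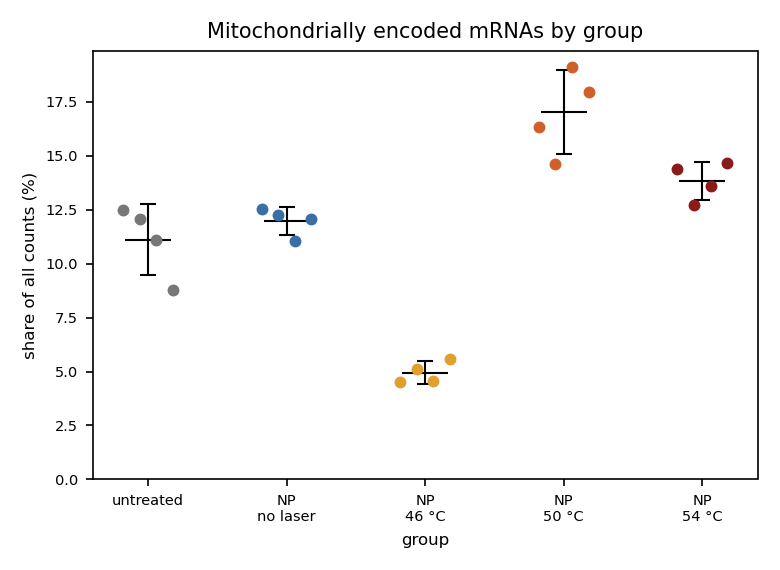
Share of all counts on the 13 mitochondrially encoded mRNAs in percent (vertical axis, linear from 0) in the 5 groups (horizontal axis), with a point per sample and bars for the mean and SD of 4 samples. The mean was 11.98% with nanoparticles alone, 4.95% at 46 °C, 17.01% at 50 °C and 13.8% at 54 °C.

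The other lists called in this step did not hold with an estimated correlation. Of 50 oxidative phosphorylation genes 3 were lower and 1 higher, with 6 lower and 1 higher adjusted over the list alone (median −0.16; adjusted p = 0.00437, and adjusted p = 0.621 with an estimated correlation), and the median was −0.327 (adjusted p = 1.58e-06) under scaling by library totals. These were UQCRQ (−0.44 ± 0.11; adjusted p = 0.0188), COX6C (−0.47 ± 0.12; adjusted p = 0.0306), ATP5F1E (−0.37 ± 0.10; adjusted p = 0.0477, chosen after its value was seen) and NDUFV1 (0.65 ± 0.17; adjusted p = 0.0321). Of 24 hypoxia and glycolysis genes GPI, a glycolytic enzyme, was higher (0.51 ± 0.13; adjusted p = 0.0205), with 3 higher adjusted over the list alone (median 0.15; adjusted p = 0.0381, and adjusted p = 0.257 with an estimated correlation), and the median was −0.023 (adjusted p = 0.192) under scaling by library totals. Of 24 NF-kB targets 2 were higher, with 3 adjusted over the list alone (median 0.07; adjusted p = 0.0493, and adjusted p = 0.607 with an estimated correlation), and scaling by library totals turned the median to −0.093 (adjusted p = 0.0466). They were NFKBIA, the IkB-alpha gene (1.06 ± 0.17; adjusted p = 2.23e-05), and NFKBIZ (1.90 ± 0.42; adjusted p = 0.00672). Scaling by library totals also ended the call of GPI (0.338; adjusted p = 0.139). GPI lost its call without 46 °C replicate 1 or 50 °C replicates 3 or 4 (adjusted p up to 0.124), UQCRQ (up to 0.136), COX6C (up to 0.215) and NDUFV1 (up to 0.215) without 46 °C replicates 1 or 2 or 50 °C replicates 1, 3 or 4, NDUFV1 also without 46 °C replicate 3, and HIST1H2AG kept its call only without 46 °C replicate 4 (up to 0.182). The NF-kB list lost its call without 46 °C replicates 3 or 4 or 50 °C replicates 1 or 2 (up to 0.321), the hypoxia list without 46 °C replicates 2 or 3 or 50 °C replicates 3 or 4 (up to 0.157), and the oxidative phosphorylation list without 46 °C replicate 2 or 50 °C replicate 3 (up to 0.0767). The NF-kB median was 0.207, 0.268 and 0 without 46 °C replicates 1, 2 and 3, and 0.039, 0.04, 0.221 and 0.213 without 50 °C replicates 1 to 4. The hypoxia median was 0.232 without 46 °C replicate 2, and that of oxidative phosphorylation −0.099 without 50 °C replicate 4.

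In all, 71 genes were higher and 74 lower at 50 than at 46 °C, 38 and 28 of them by at least 2-fold, and replicate values did not overlap for 7.1% of genes (chance 2.86%). Within replicates 1 and 2 the counts were 126 and 110, within replicates 3 and 4 40 and 35, and with the term for the replicate pairs 169 and 172. DESeq2 called 108 and 120. The NF-kB list was called within neither pair of replicates (median 0.23 and 0.29; adjusted p = 0.357 and 0.152) and the hypoxia list within replicates 3 and 4 alone (0.08 and 0.23; 0.41 and 0.00834), and the other called lists within both. Scaling by library totals moved the median of all genes to −0.177 (−0.004 with TMM) and the share of higher calls from 49% to 11%. The 74 lower genes became 48 and 43 without 46 °C replicates 1 and 2, and 47 without 50 °C replicate 3.

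In the step from 50 to 54 °C, 1 of 15 histone genes and 1 of 13 mitochondrial mRNAs were lower at 54 °C. The histone list, a sign of RNA quality, was also called with an estimated correlation (adjusted p = 0.000124), and the mitochondrial list was not (adjusted p = 0.176 with an estimated correlation). HIST1H2AG had −3.59 ± 0.62 (SE, n = 4 per group; adjusted p = 0.000377), MTRNR2L10 −3.16 ± 0.57 (adjusted p = 0.000787), LINC00324 −2.77 ± 0.31 (adjusted p = 3.67e-05) and BCL6 −2.60 ± 0.23 (adjusted p = 6.43e-12). Higher at 54 °C were CDC20, an activator of the anaphase-promoting complex (0.85 ± 0.16; adjusted p = 0.00206), NORAD, a noncoding RNA (0.68 ± 0.14; adjusted p = 0.00714), TARDBP, an RNA-binding protein gene (0.86 ± 0.19; adjusted p = 0.017), and RTF1, a transcription elongation factor (0.69 ± 0.16; adjusted p = 0.0387). Of 15 histone genes 1 was lower and 7 adjusted over the list alone (median −1.47; adjusted p = 3.48e-16, and adjusted p = 0.000124 with an estimated correlation), with HIST1H1E at −0.99 ± 0.28 (adjusted p = 0.188). Of the 13 mitochondrial mRNAs 1 was lower, MT-CO1 (−1.41 ± 0.24; adjusted p = 0.017), and 7 adjusted over the list alone (median −0.39; adjusted p = 3.67e-14, and adjusted p = 0.176 with an estimated correlation), with MT-ND2 at −0.44 ± 0.11 (adjusted p = 0.177). Of 79 ribosomal protein genes 1 was lower, RPS2 (−0.42 ± 0.09; adjusted p = 0.0174), and 9 adjusted over the list alone (median −0.12; adjusted p = 2.03e-07, and adjusted p = 0.745 with an estimated correlation), with a median of −0.027 (adjusted p = 0.00618) under scaling by library totals. Of 8 nuclear long noncoding RNAs 0 passed and 1 was higher adjusted over the list alone (median 0.29; adjusted p = 0.0181, and adjusted p = 0.256 with an estimated correlation), with NEAT1 at 0.60 ± 0.19 (adjusted p = 0.352), and the median was 0.17 without 50 °C replicate 2.

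In all, 7 genes were higher and 17 lower at 54 than at 50 °C, 0 and 16 of them by at least 2-fold, and replicate values did not overlap for 5.13% of genes (chance 2.86%). Within replicates 1 and 2 the counts were 14 and 24, within replicates 3 and 4 4 and 18, and with the term for the replicate pairs 33 and 36. DESeq2 called 17 and 25. The ribosomal proteins were called within replicates 1 and 2 alone (median −0.22 and −0.010; adjusted p = 2.03e-19 and 0.695) and the nuclear RNAs within replicates 3 and 4 alone (0.16 and 0.27; 0.155 and 0.0369), and the histone and mitochondrial lists within both. The share of higher calls was 29.2%, and 57.9% when libraries were scaled by their totals. The 7 higher genes became 3 without 50 °C replicates 1, 3 or 4 or 54 °C replicate 1, 2 without 54 °C replicate 2 and 4 without 54 °C replicate 3. CDC20 and HNRNPA2B1 were among them each time, and the rest were TARDBP, NORAD or RTF1. HNRNPA2B1 was chosen after its value was seen. TARDBP lost its call without 50 °C replicates 3 or 4 or 54 °C replicates 1 or 2 (adjusted p up to 0.199), NORAD without 50 °C replicates 1 or 4 or 54 °C replicate 2 (up to 0.0672), and RPS2 without 50 °C replicates 1, 3 or 4 or 54 °C replicates 1 or 2 (up to 0.243). RTF1 kept its call only without 50 °C replicate 4 (up to 0.239), and MT-CO1 only without 50 °C replicate 2 or 54 °C replicate 4 (up to 0.092). Without 54 °C replicate 4 the adjusted p of the nuclear RNA list was 0.0884.

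MYC, the transcription factor named in the series title (ENSG00000136997; chromosome 8, 127735434 to 127741434, GRCh38), was not called in any of the 6 comparisons with edgeR. Its mean level was 22.1 ± 4.37 CPM (SD, n = 4) with nanoparticles alone, 27.1 ± 16.9 at 46 °C, 25.3 ± 8.68 at 50 °C and 35.1 ± 3.90 at 54 °C. At 54 °C its log2 fold change against nanoparticles alone was 0.67 (95% interval 0.015 to 1.32; adjusted p = 0.866, unadjusted p = 0.0451), and all 4 samples lay above all 4 with nanoparticles alone. Against nanoparticles alone it had 0.29 ± 0.33 at 46 °C (adjusted p = 0.845) and 0.20 ± 0.33 at 50 °C (adjusted p = 0.897). Nanoparticles alone against untreated cells gave 0.20 ± 0.34 (adjusted p = 1). The steps gave −0.09 ± 0.33 from 46 to 50 °C (adjusted p = 0.973) and 0.47 ± 0.32 from 50 to 54 °C (adjusted p = 0.959). The sign turned at 46 °C within replicates 1 and 2 (−0.68, against 0.83 within replicates 3 and 4), and to −0.13 without 46 °C replicate 4. It turned at 50 °C within replicates 3 and 4 (−0.16) and to −0.056 without 50 °C replicate 1. For 50 against 46 °C it turned within replicates 1 and 2 (1.19), in limma-voom (0.089) and, up to 0.33, without 46 °C replicate 4. For nanoparticles alone it was −0.002 without untreated replicate 3.

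**Figure D4:**
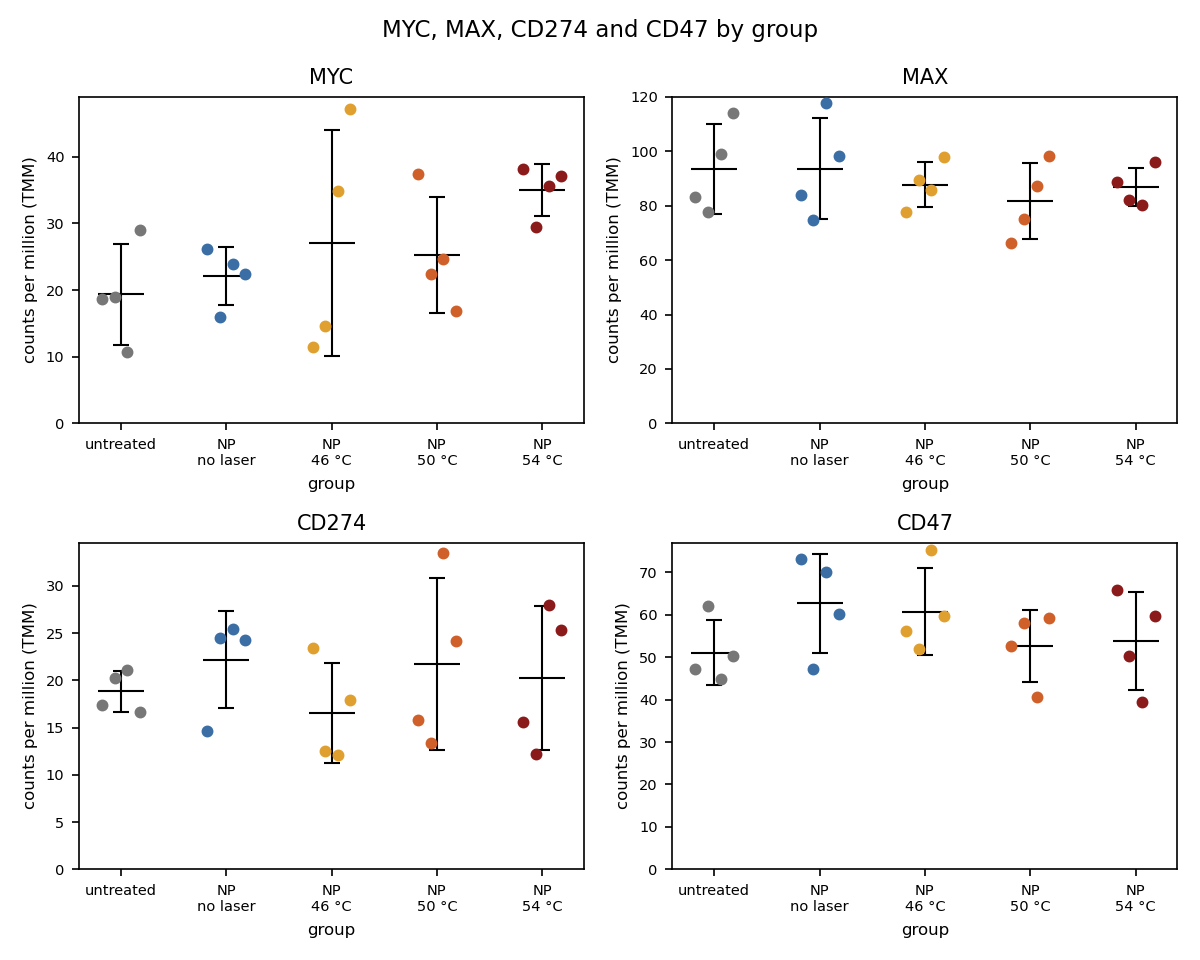
Normalised counts of MYC, MAX, CD274 and CD47 in CPM (vertical axes, linear from 0) in the 5 groups (horizontal axes), with a point per sample and bars for the mean and SD of 4 samples. The mean of MYC was 22.1 CPM with nanoparticles alone and 35.1 CPM at 54 °C, and no gene in the plot was called in any comparison.

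MAX, CD274 and CD47 were not called in any of the 6 comparisons. Their smallest adjusted p values were 0.753 for MAX at 50 °C (−0.19 ± 0.17), 0.726 for CD274 at 46 °C (−0.42 ± 0.34) and 0.728 for CD47 at 50 °C (−0.25 ± 0.20). The 55 measured growth genes known to respond to MYC were not called as a list in any comparison (smallest adjusted p = 0.412, nanoparticles alone against untreated cells), nor were the 10 genes of the MYC and MAX network (0.0672, 54 °C, median 0.22; 0.0447, 0.029 and 0.0466 without nanoparticle-alone replicate 4 and 54 °C replicates 2 and 3), the 12 checkpoint ligands (0.668, 50 against 46 °C) or the 19 class I antigen presentation genes (0.164, 50 °C). Other lists not called, with their smallest adjusted p, were endoplasmic reticulum chaperones (0.206), integrated stress response (0.404), interferon-stimulated genes (0.695), cell death effectors (0.115), NRF2 targets (0.173), iron handling (0.5), metallothioneins (0.809), cholesterol synthesis (0.187), lysosome genes (0.852), G2/M genes (0.119), DNA replication genes (0.0753), proteasome subunits (0.194), splicing regulators (0.404) and luminal breast markers (0.194). Leaving out 1 library could call the G2/M (down to 0.000782), DNA replication (0.012), cholesterol (0.0363) and proteasome lists (0.0411). The median, the mean and the test of a list differed in sign for 10, 4, 2, 6, 8 and 7 of the 28 lists in the comparisons in the order above, and 0 of these lists were called. Of the other cell types, macrophage markers had 2 of 16 genes past the filter (highest level in any library 21.4 CPM), lymphocyte markers 0 of 13 (2.46 CPM), blood markers 1 of 14 (6.47 CPM) and fibroblast markers 2 of 10 (7.96 CPM).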

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

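The tests of depth, swapped labels and replicate pairs for the heat shock pattern, of library totals for the mitochondrial pattern, and the matched comparison of small RNA hosts, were chosen only after the result was seen. The other tests were written before.

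A sample counted as far from the others of its group when its gap to the nearest of them, as a part of the group's range, passed the 95% critical value of Dixon's test, which chance does in about 1 of 20 groups of 4. Of 365 sets of 4 values, 20 met this. The values were 60.59 on the third principal component for 46 °C replicate 3 and −67.73 on the fourth for 54 °C replicate 4. With nanoparticles alone, replicate 4 had 1741 CPM of ACTB and 14000 CPM of MT-ND2, and replicate 1 had 14.59 CPM of CD274. Untreated replicate 3 had 340.4 CPM of RBM3. At 46 °C, replicate 2 had 61.76 CPM of RMRP, 1585 CPM of ATP5F1E, 41.47 CPM of NFKBIA and 105.6 CPM of HIST1H1C, replicate 4 had 14.95 CPM of HIST1H1E and 150.5 CPM of FOS, and replicate 1 had 6690 CPM of MT-ND2. At 50 °C, replicate 2 had 6.205 CPM of HMOX1, 113.7 CPM of DDIT4 and 43.93 CPM of IL1A, replicate 4 had 40.41 CPM of HIST1H2AG, and replicate 1 had 94.41 CPM of IRF1. At 54 °C, replicate 2 had 27.65 CPM of EGR1 and replicate 4 had 15.81 CPM of BCL6. The most such values in a library were 4, in 46 °C replicate 2.

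The heat shock and immediate-early lists rose at 46 °C and were not called at 50 °C (adjusted p = 0.383 and 0.0554) or 54 °C (0.524 and 0.171). Lower depth of the 46 °C libraries was argued against, since the heat shock list kept an adjusted p of 7.01e-52 with all libraries thinned to the smallest. A swap of 2 single library labels between the 46 °C group and another was argued against (an exchange of whole groups was not tested and stays open), since the highest summed level of the list outside the 46 °C group was 14647 CPM and the 46 °C libraries ran from 24369 to 30029 CPM. Each group holds both replicate pairs, so a difference between the pairs could not by itself give this rise, and the design left nothing to test there. The fits of each pair alone show only that the heat shock list rose in both, with a larger adjusted p of 2.77e-56. A hypothesis that stays open is that the response needs transcription that may not have gone on in cells heated to 50 or 54 °C, which these data do not test, and light was not separated from heat.

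Of 13 mitochondrially encoded mRNAs 9 fell at 46 °C and 6 rose at 50 °C, where the list was not called with an estimated correlation (adjusted p = 0.102), and the median difference between 50 and 46 °C was 1.913 on the log2 scale. Sizes and TMM from nuclear genes gave medians of −1.24 at 46 °C and 0.608 at 50 °C, which moved nothing and so decides nothing about mitochondrial reads in the library sizes. Taking these reads out of the library totals, without TMM, shifted the medians by −0.111 to −1.298 at 46 °C and by 0.089 to 0.57 at 50 °C, well below their size, which argues against them as the whole cause. At 46 °C the 11 nuclear copies counted changed by −1066.6 CPM and the mRNAs by −70318 CPM, a gain of −1.52% of the loss. The copies named here, the MTRNR2L genes, copy a mitochondrial ribosomal RNA and not these mRNAs. Copies of the mRNAs may not be among the genes counted, so reads moved to nuclear copies stay open. Whether stability, transcription or loss of cytoplasmic RNA could account for the mitochondrial pattern was not tested.

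Genes that rose at 50 °C often spanned annotated small structured RNAs on their strand. Of 62 such genes with coordinates, 20 (32.3%) did, against a median of 8.1% in 10000 random sets matched on length and level (permutation p = 1e-04, the smallest these sets can give). With a stricter definition, without the gene itself or Rfam pieces and chosen after the values were seen, 16 (25.8%) did, against 6.5% (permutation p = 1e-04, again the smallest). Gene length alone was argued against, since 1.6% held such an RNA on the opposite strand, inside the unmatched range of 1.6% to 12.9%. RMRP and TERC, themselves small structured RNAs, were counted under identifiers of long RNAs, and the identifiers annotated as small structured RNAs, 5132 in all, were not among those counted, so a candidate explanation is that reads of these RNAs, perhaps with tails added to them, were counted for the longer gene.

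The number of genes called was compared with that in the 35 splits of each set of 8 libraries into 4 and 4, the real split included. At 46 °C 1 split, the real one, gave as many as 117 genes, and the highest other gave 3. At 50 °C it was 1, with 148 genes against 0, and for 50 against 46 °C 1, with 145 genes against 22 in the split of replicates 1 and 2 from 3 and 4. Since the replicate pairs differ, the 35 splits cannot exclude chance. The 18 splits of each comparison that divide replicates 1 and 2 evenly are too few for a share under 0.05, and in these the highest other gave 3 genes at 46 °C, 0 at 50 °C and 0 for 50 against 46 °C. For nanoparticles alone all 35 splits gave at least the real 0, and the split by replicate pair gave 68. At 54 °C 2 splits gave at least 15 genes, and for 54 against 50 °C 2 gave at least 24. In both the other was the split by replicate pair, with 40 and 87 genes, and the remaining splits gave at most 0. Nor is chance excluded there, and the evenly divided 18 are again too few, with 0 genes in the highest other. The split by pair gave several times the real count, a structure of the samples, and with the term for the replicate pairs the counts were 26 higher and 17 lower at 54 °C, and 33 and 36 for 54 against 50 °C.

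Counts of called lists cannot exclude chance, since many splits keep 3 libraries of a group or divide the replicate pairs unevenly. In report order, 5, 7, 5, 2, 7 and 4 lists were called, and at most 10, 10, 10, 11, 13 and 11 in others. In the evenly divided 18, too few for a share under 0.05, others gave at most 4, 7, 6, 3, 6 and 4. Those with 2 of each group gave at most 3, 1, 1, 3, 0 and 2.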

How the results depend on the processing

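The replicate-pair term, each pair alone and DESeq2's own filter were chosen after seeing the data, the others before. Naming genes mostly without replicate overlap made reversals unlikely. Of 103 called values of named genes, 2416 values under alternatives and left-out libraries gave 0 reversals, 292 that missed the threshold and 2124 on the same side. Of 30 called lists, 595 such values gave 1 reversal of the test's direction, 81 that missed the threshold and 513 on the same side. The median of a called list turned sign in 5 values, the reversal among them, though the test kept its direction in the others: mitochondrial mRNAs with nanoparticles within replicates 1 and 2 (−0.026) and, scaled by library totals, ribosomal proteins at 50 °C (−0.024) and, for 50 against 46 °C, hypoxia genes (−0.023) and NF-kB targets (−0.093). Of 116 named genes and comparisons not called, 49 turned sign under at least 1 alternative. At 2-fold the simulations recovered at most 49.3% of changed genes, in 54 °C against nanoparticles alone (11780 genes), and least, 26.9%, in 54 against 50 °C (11799 genes). They did not vary depth, and what fewer counts changed is given with the thinning. Where no cause is named below, the cause was not tested.

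Comparisons are named by temperature, against nanoparticles alone unless another is given, and nanoparticles stands for nanoparticles alone against untreated cells. Scaling by library totals gave 227 genes lower at 50 °C, 46 higher and 374 lower for 50 against 46 °C, and 22 higher for 54 against 50 °C. It turned the log2 fold change of MAX to −0.006 (nanoparticles), CD47 to 0.009 and CIRBP to 0.044 (46 °C), HSPH1 to −0.052 and CIRBP to −0.005 (50 °C), CIRBP to −0.048 and HMOX1 to −0.029 (50 against 46 °C), and HSPA1B to 0.047 and EGR1 to 0.04 (54 against 50 °C). DESeq2 size factors in edgeR turned MAX to −0.003 (nanoparticles), the stricter filter to −0.002 and the DESeq2 Wald test to −0.003. Without a filter, 1 gene was higher (ALDOA) and 1 lower (SPOCK1) with nanoparticles, 97 were higher at 50 °C, and 26 higher and 12 lower at 54 °C, where more genes were tested. ALDOA and SPOCK1 were chosen after their values were seen.

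DESeq2 called 115 genes higher and 77 lower at 46 °C, 140 and 148 at 50 °C, 25 and 11 at 54 °C, 108 and 120 for 50 against 46 °C, and 17 higher for 54 against 50 °C. With its own filter it called 115 and 77, 140 and 148, 25 and 11, 127 and 150, and 31 and 29 in the same order, gave MAX −0.003 (nanoparticles), and gave no adjusted p in 16 cases of named genes. Limma-voom called 113 higher at 50 °C, 14 higher at 54 °C, and 11 higher and 34 lower for 54 against 50 °C. It turned MAX to −0.009 and FOS to −0.592 (nanoparticles), CIRBP to 0.014 (46 °C), FOS to −0.107 (50 °C) and MYC to 0.089 (50 against 46 °C).

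Fitting only the 8 samples compared gave 104 genes higher at 50 °C, and 4 higher (CDC20, HNRNPA2B1, HNRNPA3 and NORAD) and 27 lower for 54 against 50 °C. A threshold of 2-fold left 43 higher and 20 lower at 46 °C, 34 and 21 at 50 °C, 38 and 28 for 50 against 46 °C, and 0 higher for 54 against 50 °C, where edgeR had 731 genes at an unadjusted p under 0.05. Thinning to the smallest library, which leaves fewer counts, gave 3 lower at 54 °C (AC007381.2, BCL6 and PPP3R1), 4 lists at 54 °C and 4 higher for 54 against 50 °C (CDC20, HNRNPA2B1, NORAD and TARDBP). Thinning also turned MAX to −0.042 (nanoparticles), FOS to −0.15 (50 °C), and CD274 to 0.243, CD47 to −0.059, DNAJB1 to 0.008 and JUN to −0.063 (54 against 50 °C). Genes in parentheses outside the naming rule were chosen after their values were seen.

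With untreated cells as the baseline, 120 genes were higher at 50 °C. Called genes that moved by over 1.5 times included UQCRQ (0.289), COX6C (0.194), ATP5F1E (0.257) and MALAT1 (0.669) at 46 °C, HIST1H2AG (2.268), EIF3C (1.532), MALAT1 (0.831) and HIST1H1E (0.995) at 50 °C, and POLR2J3 (0.672), NDRG1 (0.393) and PPP3R1 (−0.537) at 54 °C. Of these HIST1H2AG and HIST1H1E kept the call (adjusted p = 0.0262 and 0.0479). Not called before, CD47 was 0.249 and CIRBP 0.013 at 46 °C, CD274 0.204, CD47 0.043 and HSPH1 −0.003 at 50 °C, and CD274 0.102 and CD47 0.075 at 54 °C. Besides lists named in the report, medians moved by over 1.5 times for nuclear RNAs without a filter (0.473 at 46 °C, 0.569 at 50 °C and 0.178 for 54 against 50 °C; adjusted p = 0.00109, 0.0563 and 0.0994) and with thinning (0.507 at 50 °C; adjusted p = 0.00646), and for NF-kB targets in 50 against 46 °C with the replicate block (0.12; adjusted p = 0.0937), the term for the pairs (0.133; 0.0951) and thinning (0.039; 0.0666). Of lists not called, the immediate-early list at 50 °C was called with no or a stricter filter, the 8 samples alone, the replicate block (adjusted p = 0.0349, 0.0482, 0.023 and 0.0136) and as given in the report, and the MYC and MAX network and mitochondrial mRNAs at 54 °C with thinning (both 0.0377). The block also called hypoxia genes (0.0499) and YAP and SRF targets (0.0105) at 50 °C. With an estimated correlation 0 lists were called for nanoparticles, 4 at 46 °C, 1 at 50 °C, 1 at 54 °C, 4 for 50 against 46 °C and 1 for 54 against 50 °C.

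The replicate block gave 161 genes higher and 108 lower at 46 °C, 152 and 181 at 50 °C with 8 lists, 27 and 19 at 54 °C, 174 and 179 for 50 against 46 °C, and 32 and 36 for 54 against 50 °C. The numbers do not pair the samples: deviations of samples with the same number in different groups correlated at 0.022 to 0.066, with a median of 0.041, and 9 of 20 libraries correlated best with their own number. The term for the replicate pairs gave 157 and 106 at 46 °C, 150 and 180 at 50 °C with 8 lists, 26 and 17 at 54 °C, 169 and 172 for 50 against 46 °C, and 33 and 36 for 54 against 50 °C, with MAX at −0.001 (nanoparticles).

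Replicates 1 and 2 alone, which are fewer samples, gave 4 genes higher and 3 lists for nanoparticles, 147 higher and 114 lower at 46 °C, 10 lists at 50 °C, 4 lists at 54 °C, 126 higher for 50 against 46 °C and 14 higher for 54 against 50 °C. RMRP with nanoparticles and HSPA6 at 50 °C had 0 counts there, so their folds are not given. MT-CO2 had 0.32 and MT-CO3 0.382 at 50 °C, and HIST1H2AG 3.434 for 50 against 46 °C, and at 50 °C the medians were 0.87 for NF-kB targets, 0.401 for mitochondrial mRNAs and 0.628 for nuclear RNAs. Signs turned for MT-CO2 (−0.018), MAX (−0.021), DNAJB1 (0.033), HSPH1 (0.261) and EGR1 (−0.247) with nanoparticles, MYC (−0.681) and MAX (0.076) at 46 °C, RBM3 (0.047) at 50 °C, and MAX (0.107) and ATF3 (0.068) at 54 °C. They also turned for MYC (1.188), CD274 (−0.296) and CD47 (0.038) in 50 against 46 °C, and JUN (−0.07) and RBM3 (−0.008) in 54 against 50 °C.

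Replicates 3 and 4 alone gave 1 gene higher (ALDOA), 1 lower (MALAT1) and 3 lists for nanoparticles, 45 higher, 19 lower and 4 lists at 46 °C, 40 and 21 at 50 °C, 16 higher at 54 °C, 40 and 35 for 50 against 46 °C, and 4 higher for 54 against 50 °C. UQCRQ had 0.242 and ATP5F1E 0.246 at 46 °C, NDRG1 0.352 and MT-ND6 −1.49 at 54 °C, and immediate-early genes a median of 1.098 at 46 °C. Signs turned for HSPA1A (−0.486), HSPA1B (0.067), FOS (−0.566), JUN (−0.142), CIRBP (−0.078) and the ribosomal protein list (median 0.033) with nanoparticles, and CD47 (0.051) and CIRBP (0.076) at 46 °C. They turned for MYC (−0.158), CD274 (0.211), HSPA1A (0.291), DNAJB1 (0.11), FOS (−2.402) and ATF3 (−0.158) at 50 °C, CD274 (0.105) and HSPA1A (0.208) at 54 °C, and MAX (0.011) and HMOX1 (−0.135) in 50 against 46 °C. In 54 against 50 °C they turned for TUG1 (−0.141), MAX (−0.064), CD47 (−0.002), HSPA1A (−0.082), HSPA1B (0.02), HSPH1 (−0.043) and FOS (1.887). FOS had 1 count in 50 °C replicates 3 and 4, so the size of its values there rests on the fit.

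Leaving out each library in turn gave 67 values of named genes with a turned sign, 173 that missed and 9 that gained the threshold, and 1455 on the same side, and of list values 35 missed the threshold and 205 stayed on the same side. For nanoparticles the genes higher ran from 0 to 1 and the lists from 2 to 4. Log2 fold changes ran from −0.002 to 0.445 for MYC, −0.125 to 0.109 for MAX, −0.144 to 0.099 for HSPA1B, −0.127 to 0.005 for DNAJB1, −0.231 to 0.078 for HSPH1, −1.231 to 0.442 for FOS, −0.241 to 0.498 for EGR1, −0.101 to 0.19 for JUN and −0.077 to 0.113 for CIRBP. At 46 °C the genes lower ran from 26 to 51, MYC from −0.13 to 0.543, MAX from −0.185 to 0.035, CD47 from −0.161 to 0.04 and CIRBP from −0.209 to 0.08. At 50 °C the genes lower ran from 33 to 69, the lists from 5 to 10, MYC from −0.056 to 0.343, CD274 from −0.327 to 0.136, DNAJB1 from −0.106 to 0.015, HSPH1 from −0.027 to 0.111, FOS from −0.414 to 1.474, ATF3 from −0.053 to 0.771 and RBM3 from −0.077 to 0.063. At 54 °C the genes higher ran from 4 to 10, the genes lower from 3 to 6, the lists from 2 to 5, MAX from −0.2 to 0.021, CD274 from −0.329 to 0.049 and ATF3 from −0.895 to 0.038. For 50 against 46 °C the genes lower ran from 43 to 64, MYC from −0.343 to 0.33 and HMOX1 from −0.146 to 0.395. For 54 against 50 °C the genes higher ran from 2 to 10, CD274 from −0.298 to 0.194, CD47 from −0.072 to 0.155, HSPA1B from −0.284 to 0.133, HSPH1 from −0.037 to 0.121, EGR1 from −0.335 to 0.129, JUN from −0.01 to 0.162 and CIRBP from −0.091 to 0.185.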

Other observations

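The overlaps of calls below were tested only after the calls were seen.

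Genes that rose at different temperatures overlapped when the comparisons used different control groups, which removes the shared controls. Of 75 genes higher at 46 °C than with nanoparticles alone and 120 higher at 50 °C than in untreated cells, 18 were shared where 0.74 would be by independence (one-sided Fisher's exact p = 1.28e-20). They included LINC00324, NEAT1, RMRP, ZNF277, SQSTM1, an autophagy receptor, the stress-induced GADD45A, and the cytokines IL1A and IL1B. Of the 42 lower at 46 °C and 115 lower at 50 °C, 6 were shared (CDC20, FOXN3, HNRNPDL, ID1, RBM25 and ZNF286A; 0.4 by independence, exact p = 2.51e-06). Exchanging the control groups gave 14 shared higher genes (0.33 by independence, exact p = 8.52e-20), and 2 shared lower genes, FOXN3 and RBM25 (0.22 by independence, exact p = 0.0205). CDC20, HNRNPDL, ID1 and ZNF286A were not shared that way. LINC00324, NEAT1 and ZNF277 were shared by 46 °C against nanoparticles alone and 54 °C against untreated cells (3 genes, 0.04 by independence, exact p = 7.77e-06). These genes were chosen after their values were seen, and genes are not independent of each other.

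Genes that hold a small structured RNA on their strand made up 15.1% of the genes higher at 46 °C with coordinates (permutation p = 0.0281 against matched random sets) and 44.4% of the 9 higher at 54 °C (permutation p = 0.0039). With the stricter definition, also chosen after the values were seen, neither p was under 0.05: the share was 8.2% at 46 °C (permutation p = 0.311) and 22.2% at 54 °C (AC007952.4 and ZNF277; permutation p = 0.104). Among the genes lower at 54 than at 50 °C were the snoRNA and small RNA hosts CSKMT (−2.36 ± 0.24), WDR74 (−1.85 ± 0.21), ZNF277 (−1.96 ± 0.26) and EIF4A2 (−1.48 ± 0.13), on the log2 scale with standard errors and 4 samples per group. They were chosen after their values were seen.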
